A study of Mus musculus with 4 samples.

How the data were processed

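Single-cell gene expression was measured in 4 libraries of CD8 T cells from the tumour-draining lymph node of mice, 1 library in each of 4 groups: B16F10 control, B16F10 treated, 4T1 control and 4T1 treated. Per the labels' protocols, tumours were implanted, mice received HCW9218 or saline, nodes were taken on day 5 after the dose, and live CD8 cells were sorted after a bead enrichment and loaded for 5′ capture on the 10x Genomics platform. The dose is stated as 3 mg/kg for the B16F10 mice, and material from 3 mice was pooled, per the series description. The strain and the dose of the 4T1 mice are not given in the sources used here. The series description speaks of 3 samples per group, while 1 library per group was analysed here, so a difference within a model has no replicate check.

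The authors' values are raw UMI counts per gene and cell barcode, with no normalization, in filtered matrices made with Cell Ranger 7.0.0 on mm10, per the submitters' processing notes and the deposited file headers. Each matrix lists 32285 genes. Whether intronic reads were counted, and which gene annotation was used, is not given in the sources used here. Gene positions are from GENCODE vM21 on GRCm38/mm10, matched by Ensembl gene identifier. T and B cell receptor libraries were not analysed here. Results for some genes are not reported here.

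The filtered matrices held 22964 and 28563 barcodes in the B16F10 control and treated libraries, and 19791 and 25673 in the 4T1 control and treated libraries. Barcodes with under 500 detected genes (248, 373, 575 and 968 in that order) or over 10% mitochondrial UMIs (14, 18, 11 and 21) were removed. Scrublet, as run in Scanpy 1.11.5, set its automatic threshold so that it marked 0, 6202, 0 and 246 barcodes, which is no working call. It was replaced, after this had been seen, by a lineage rule that removed barcodes with at least 3 T cell UMIs together with at least 5 B cell or 3 myeloid UMIs. The lineage rule removed 312, 530, 334 and 671 barcodes, or 1.37%, 1.88%, 1.74% and 2.72% of those that passed quality. Doublets of a pair of CD8 T cells cannot be called this way.

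Cells of all 4 libraries were clustered together in Scanpy with the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9) on 30 principal components of 2000 variable genes, centred within each tumour model, with 15 neighbours and resolution 0.8. Clusters were named by markers fixed before the data were examined. The scoring thresholds behind the names were set after the clusters had been seen. They were revised one time, after the alternative clusterings had been seen. All main names were the same under the first and the revised scoring. Clusters of a median UMI count below 0.35 of their libraries' median that met the scoring of no other lineage stayed unnamed and were left out of the CD8 T cells. The B cell genes Ebf1 and Bank1 were among the leading 10 genes of 1 of them. They held 0.813% and 2.47% of all cells in the B16F10 control and treated libraries, and 0.726% and 1.49% in the 4T1 control and treated libraries. Single cells in CD8 clusters with at least 5 B cell, 3 myeloid or 5 erythroid UMIs, or with Cd4 and no Cd8 UMIs, were left out too. These 3 limits were set after the data had been seen.

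UMI counts were summed over the CD8 T cells of each library. Treated libraries were compared with control libraries over both models with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust quasi-likelihood F test, two-sided), with tumour model as a block. This leaves 1 residual degree of freedom, the difference between the models in the treatment effect, and the fit borrows its spread across genes. Its errors and adjusted p-values thus measure how alike the models responded, not the spread between mice or between libraries of a group. A gene that moved the same way in both models by unlike amounts may therefore not pass. Adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. The fit was tested on simulated counts of 15862 genes at the real means and library sizes. It recovered 49 of 50 genes changed 1.5-fold and 50 of 50 at each of 2-fold, 4-fold and 8-fold, with 4 false calls. The changed genes were drawn at 10 CPM or more, each had the same fold in both models, and the spread followed the fitted trend. So the simulation does not show how well genes with unlike folds in the models are recovered, nor their rate of false calls. Within a model there is no test. Its log2 ratios of CPM, which are UMI counts scaled by the library total times its TMM factor, carry 95% exact intervals from the UMI counts, and shares of cells carry exact binomial (Clopper-Pearson) intervals. All such intervals cover counting error only. Levels given as a percent of those in B-like cells were scaled by the library total alone. The range given with a ratio of shares joins the outer ends of both intervals.

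The comparisons, tests, markers, gene lists and most alternatives were fixed before the data were examined. The 27 gene lists name cell types, states and pathways, and 21 of them had at least 3 genes at a mean of 1 CPM or more. The median log2 ratio of each of these was set against 10000 random lists of the same size drawn from 20 expression bins, and its percentile describes these libraries only. The text names genes by a rule. These are, in each direction, the 12 genes past the threshold at a mean of 10 CPM or more with the largest smaller-of-both-models ratio. Added to them are the 6 largest in each direction per model at 10 CPM or more, without receptor segment genes and Xist. Members of the lists, 4 genes of the sort and the genes of the UMI shares are named as well. For shares of cells with a UMI, each cell was thinned to 2500 UMIs and shallower cells were left out. Classes with at least 100 cells in every library were tested separately in the same way.

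Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, no block, all cells that passed quality, doublets kept, cells picked by a Cd8a or Cd8b1 UMI, equal depth (summed UMIs per library drawn down to the smallest, with UMIs per cell not matched), resolutions 0.5 and 1.2, each model clustered separately, and a stricter quality filter of 1000 genes and 5% mitochondrial UMIs. Alternatives chosen after the data had been seen were removal of cells with a doublet score above 0.25, cycling cells left out, the unnamed clusters kept, clustering without the genes that responded, the first scoring of names, and other cells or scaling for the correlation between models. The setting with doublets kept clustered the cells anew and also kept single cells of CD8 clusters with UMIs of other lineages. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 did the remaining steps.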

Results

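The series asks how HCW9218 acts on CD8 T cells of the lymph node that drains a tumour. HCW9218 is a fusion protein complex that carries interleukin 15, a growth and survival signal of memory CD8 T cells and natural killer (NK) cells, together with the outer part of the receptor for transforming growth factor beta (TGF-β), which binds and neutralises TGF-β. B16F10 is a mouse melanoma cell line and 4T1 a mouse mammary carcinoma cell line. Gene expression was counted in single sorted cells of 1 control and 1 treated library per tumour model. The libraries held 141918656 UMIs in the B16F10 control, 170871840 in the B16F10 treated, 136358848 in the 4T1 control and 165821216 in the 4T1 treated group. After doublet removal 22390, 27642, 18871 and 24013 cells remained in that order. CD8 T cells made up 89.2%, 85.9%, 84.2% and 79.0% of them, or 19983, 23745, 15882 and 18978 cells. Their summed counts were 127546624, 148025552, 114509898 and 131926090 UMIs, with a median per cell of 5369, 5335, 6015 and 5724. The genes of the sort stood level between treated and control CD8 T cells. Cd8b1 was at 1375 and 1381 CPM in the B16F10 control and treated libraries and at 1309 and 1382 CPM in 4T1, with an adjusted p of 0.703 over both models. For Cd8a and Cd3e the adjusted p was 0.877 and 0.527. Cd4 was near the floor, at 0.887 and 1.31 CPM in B16F10 and 2.02 and 3.47 CPM in 4T1 (adjusted p 0.0681). The clusters were named in part by how many cells had Cd8b1, and cells with Cd4 and no Cd8 UMIs were left out. These levels therefore do not check the sort itself.

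The first comparison asked which genes the treatment moved in the same way in both tumour models. Genes of cell division rose in treated CD8 T cells. The glucocorticoid-induced genes Tsc22d3 and Ddit4 fell, together with the homing receptor gene Ccr9 and the ribosomal protein genes Rps29 and Rpl38. Of 16061 genes tested, 390 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with the model as a block, 291 higher and 99 lower. The count was 38 (26 shared) with all cells that passed quality, 254 with doublets kept and 1484 without the filter on low counts. The last of these fits gave most genes a spread shared across genes, with none of their own. With all cells 13 of the 24 genes named in this and the next paragraph no longer passed. Among genes past the threshold at a mean of 10 CPM or more, the largest rise by the smaller of both model ratios was that of Stmn1 and Nusap1. Stmn1, which encodes a protein that destabilises microtubules (chromosome 4, 134468320 to 134473843, mm10), went from 16.9 to 42.4 CPM in B16F10 and from 44.4 to 91.0 CPM in 4T1 (block log2 1.18 ± 0.0778 SE, adjusted p 0.00638). Nusap1, a spindle protein gene (chromosome 2, 119618298 to 119651244), rose from 4.40 to 13.1 CPM and from 8.16 to 17.1 CPM (1.31 ± 0.136, adjusted p 0.0238). Cdk1, the kinase that drives entry into mitosis, had log2 ratios of 1.34 in B16F10 and 0.88 in 4T1. Cdca8, part of the chromosomal passenger complex, had 1.17 and 0.74. Tk1, the thymidine kinase of S phase, had 1.04 and 0.69, and Tcf19, a factor linked to the G1/S step, had 0.78 and 0.72. The histone genes Hist1h2ab (1.02 and 0.71) and Hist1h1a (0.71 and 0.66) rose as well, although near-identical family members leave their counts uncertain. Also higher were the non-coding RNA Lockd (0.96 and 0.76), the small membrane protein gene Smim24 (0.68 and 0.72), the acyl-CoA thioesterase gene Acot7 (0.76 and 0.63) and 1700025G04Rik (0.97 and 0.64). The adjusted p of these 12 genes lay between 0.00402 and 0.0286. With the cycling cells left out, the block log2 of Nusap1 was -0.11 and that of Cdca8 -0.24, and Cdk1, Tcf19, Hist1h1a and Lockd no longer passed.

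Among the genes that fell was Tsc22d3. It encodes the glucocorticoid-induced leucine zipper protein GILZ (chromosome X, 140539528 to 140600659) and fell from 186 to 102 CPM in B16F10 and from 189 to 117 CPM in 4T1 (block log2 -0.77 ± 0.0509 SE, adjusted p 0.00334). Ddit4, which restrains the growth kinase mTORC1 and also responds to glucocorticoid, went from 174 to 134 CPM and from 182 to 129 CPM (-0.44 ± 0.0448, adjusted p 0.00567). Ccr9, a homing receptor for the gut that naive CD8 T cells carry, had log2 ratios of -0.48 in B16F10 and -0.43 in 4T1. Il31ra, a subunit of the interleukin 31 receptor, stood at -0.64 and -0.51, and Fgfr2, a fibroblast growth factor receptor, at -0.67 and -0.50. Tmtc2 (-0.67 and -0.72), the ubiquitin ligase gene Ccnb1ip1 (-0.61 and -0.70), the lipid kinase gene Pip5k1b (-0.47 and -0.50) and the non-coding D130009I18Rik (-0.47 and -0.47) followed. Rps29 (-0.63 and -0.43) and Rpl38 (-0.53 and -0.39) encode ribosomal proteins, and Gstp2 (-1.09 and -0.78) a glutathione transferase. The near-identical copies of these 3 genes leave their counts uncertain. Gstp2 was at 5.06 CPM in the B16F10 control and 94.3 CPM in the 4T1 control library. The adjusted p of the 12 lay between 0.00334 and 0.0143.

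**Figure D1:**
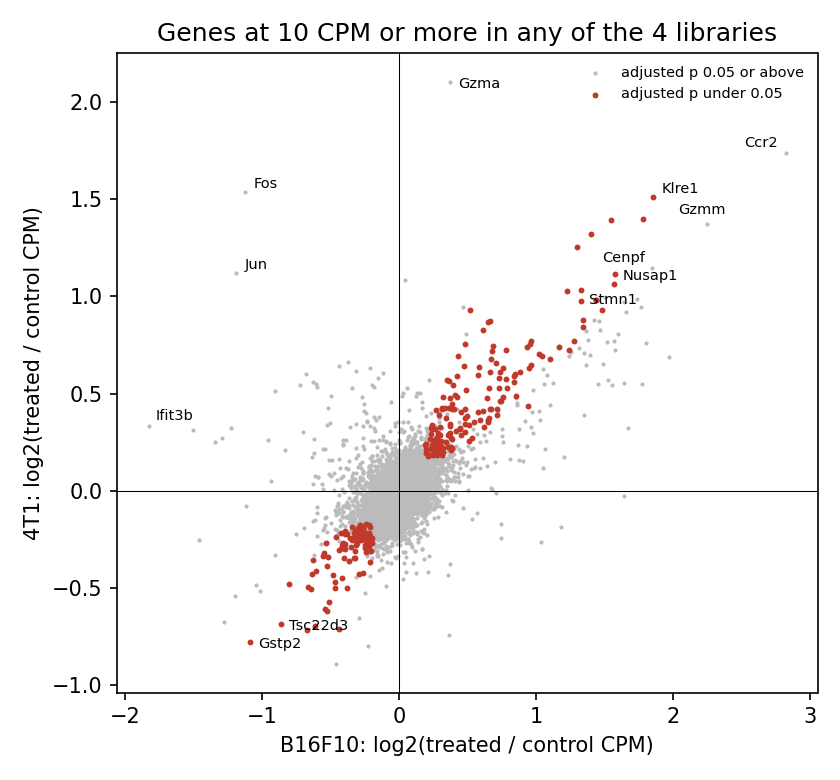
Log2 ratio of treated over control CPM in CD8 T cells for each gene at 10 CPM or more in any library, B16F10 on the x axis and 4T1 on the y axis, with genes past an adjusted p of 0.05 over both models in colour. Stmn1 and Nusap1 lie above 0 in both models, Tsc22d3 and Gstp2 below 0 in both, while Ifit3b and Jun lie on opposite sides.

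Gene lists fixed beforehand gave the next view, of programmes rather than single genes. Division, cytotoxic function and memory stood high in treated CD8 T cells of both models, and the GTPases that interferon gamma induces stood low. The cell cycle list had a median log2 ratio of 1.34 in B16F10 and 0.72 in 4T1. Of its genes 9 rose over all genes tested (Cdk1, Stmn1, Tyms, Cenpa, Aurkb, Tk1, Hmgb2, Nusap1 and Cdca8), and 19 rose adjusted over the list alone. Aurkb, a mitotic kinase, had a block log2 of 1.2 (adjusted p 0.0109), and Tyms, which makes thymidylate, 0.72 (adjusted p 0.00627). Mki67 was higher in each treated library (log2 1.66 and 0.92) without passing over both models (adjusted p 0.358). The cytotoxic effector list had medians of 0.75 and 0.32. Nkg7, a protein of cytotoxic granules, rose from 838 to 1089 CPM and from 637 to 736 CPM (block log2 0.29 ± 0.0503, adjusted p 0.0328), and the chemokine gene Ccl3 rose by 1.13 ± 0.163 (adjusted p 0.0163). Adjusted over the list alone, Nkg7, Ccl3, Ifng, Klrg1, Ccl4 and Tbx21 were the 6 higher and Id2 the 1 lower gene. Gzmb (adjusted p 0.202) did not pass, and the perforin gene Prf1 had ratios of -0.07 and -0.22. Genes of NK cells rose in the same summed counts, although an NK-like cluster had been left out of the CD8 T cells. The memory list had medians of 0.55 and 0.16. The integrin gene Itga4 fell (-0.32 and -0.21, adjusted p 0.0286). Adjusted over the list alone Plac8 was among the higher genes and Itga4 was the 1 lower gene. All 3 lists lay above the central 95% of random lists in both models.

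The list of STAT5 targets lay high in 4T1, while the place of the TGF-β targets depended on the cells used, and single members of both rose. The interleukin 2 and interleukin 15 STAT5 target list had medians of 0.03 (percentile 82.6) in B16F10 and 0.20 in 4T1, where it lay above the central 95% of random lists. Socs2, a feedback inhibitor of cytokine signalling, rose by a block log2 of 1.34 ± 0.237 (adjusted p 0.0341) from 0.213 to 0.544 CPM and from 0.384 to 0.964 CPM. Il2ra, the high-affinity chain of the interleukin 2 receptor, rose by 0.72 ± 0.0902 (adjusted p 0.0115), the survival gene Bcl2 by 0.24 ± 0.0384 (adjusted p 0.0249) and the cyclin-dependent kinase gene Cdk6 by 0.26 ± 0.0519 (adjusted p 0.0476). These 4 passed over all genes, and 7 higher and 1 lower (Ccnd3) adjusted over the list alone. Il2ra is also on the CD4 and regulatory T cell list, where Cd4, Foxp3 and Ikzf2 rose adjusted over that list alone. RNA of regulatory T cells was not told apart as a source of its rise. The TGF-β target list had medians of -0.08 (percentile 2.08) and 0.01 (percentile 85.5). In B16F10 its percentile was 7.62 with cells picked by a Cd8 UMI and 40.2 with all cells, inside the central 95% of random lists. Its member Smad3, which carries the TGF-β signal to the nucleus, rose by 0.55 ± 0.0733 (adjusted p 0.0155). Adjusted over the list alone, Smad3, Klf10, Cdkn2b and Cdkn1a were the 4 higher and Tgif1 the 1 lower gene. Itgae, a classic TGF-β target in CD8 T cells, had ratios of -0.22 and -0.06. The apoptosis regulator list had medians of 0.00 and 0.01 and 1 gene higher over all genes (Bcl2), 2 adjusted over the list alone (Bcl2 and Bcl2l1).

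Among genes of exhaustion the ectoenzyme gene Cd38 rose, while the transcripts of PD-1, LAG-3 and TOX did not pass. The inhibitory receptor and exhaustion list had medians of 0.23 and 0.09 (percentile 98.9 in 4T1). Cd38, a marker of activated and dysfunctional T cells, rose by a block log2 of 0.97 ± 0.156 (adjusted p 0.0252), and with Entpd1 made 2 higher adjusted over the list alone. Pdcd1, which encodes PD-1, had ratios of 0.22 and -0.00, Lag3 0.23 and -0.09, and Tox -0.04 and -0.12. Tigit was at 1.39 and 0.56 with an adjusted p of 0.197. The progenitor exhausted list had medians of 0.22 and 0.04 (percentile 87.0). Id3, a repressor that keeps T cells from terminal differentiation, rose by 0.40 ± 0.0401 (adjusted p 0.00516) and the chemokine gene Xcl1 by 0.42 ± 0.0562 (adjusted p 0.0134), and with Cxcr5 they made 3 higher adjusted over the list alone. The naive and quiescence list had medians of -0.06 (percentile 3.13) and -0.01 (percentile 23.4). Over all genes Id3 rose while Ccr9, Actn1 (block log2 -0.20) and the anti-proliferative gene Btg1 (-0.23) fell. Adjusted over the list alone 1 rose and 6 fell, with Lef1, Il7r and S1pr1 added. Tcf7, held by naive and central memory cells, had ratios within 0.1 of 0 on the log2 scale. In the homing and tissue exit receptor list (-0.10 and -0.06, percentiles 0.710 and 3.68) Itga4 and Ccr9 fell over all genes. Adjusted over the list alone Cxcr3 and Itgal were among the higher genes, and S1pr1, Itga4, Cxcr4, Cxcr6 and Ccr9 were the 5 lower genes.

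The type I interferon and immediate early lists had opposite signs in the models, the interferon gamma GTPase list lay low in both, and the glycolysis list lay high in both. The type I interferon list had a median of -0.63 in B16F10, with 0 of 26 genes higher, and 0.21 in 4T1, with 23 of 26 higher. The interferon gamma GTPase list had medians of -0.34 and -0.13, below the central 95% of random lists in both models. Tgtp2 fell (-0.26, adjusted p 0.0192), with a near-identical copy in Tgtp1, and 10 genes fell adjusted over the list alone, Gbp2, Irgm1 and Irf1 among them. The immediate early list had medians of -0.33 and 0.15, with 0 genes past the threshold over all genes and 0 adjusted over the list alone. Heat shock genes lay at -0.10 and -0.08 (percentiles 1.36 and 1.31). With doublets kept the percentiles were 3.12 and 3.49, and with all cells 4.05 in B16F10, inside the central 95%. In this list the chaperone genes Hsph1, Dnajb1 and Dnaja1 fell both over all genes and adjusted over the list alone (3 genes each). The glycolysis list lay at 0.10 and 0.08 (percentile 99.6 in both), with 0 genes over all genes and 5 higher adjusted over the list alone (Slc2a3, Gpi1, Pfkp, Tpi1 and Pgam1). The oxidative phosphorylation list lay at 0.01 and 0.02. Atp5k fell over all genes (-0.31, adjusted p 0.0115), and adjusted over the list alone Ndufb5 and Cox5a were the 2 higher and Cox7c and Atp5k the 2 lower genes. The cholesterol and sterol list (0.02 and 0.09, percentiles 66.0 and 98.9) and the amino acid transport and translation list (-0.01 and -0.02) had 0 genes past the threshold either way.

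Most genes of other cell types were low in the CD8 T cells, and several rose. An exception by level was the antibody gene Ighm, at 24.1% and 23.7% of its level in B-like cells in B16F10 and at 27.1% and 30.6% in 4T1. The NK cell list, with 3 measured genes, had medians of 1.04 and 1.14. The NK receptor gene Klre1 rose by a block log2 of 1.81 ± 0.130 (adjusted p 0.00334) and the adaptor gene Tyrobp by 1.09 ± 0.124 (adjusted p 0.00825), and 6 genes rose adjusted over the list alone. Klre1 was at 4.37 and 15.8 CPM in B16F10 and at 0.106 and 0.303 CPM in 4T1. The B cell list had medians of 0.56 and 0.40. Cd74, the invariant chain of class II presentation, rose from 14.6 to 22.5 CPM and from 7.75 to 13.7 CPM (adjusted p 0.00566), H2-Aa rose too (adjusted p 0.0123), and 6 genes rose adjusted over the list alone. The CD4 and regulatory T cell list had medians of 0.30 and 0.26, with Il2ra higher over all genes and 4 genes (Cd4, Foxp3, Ikzf2 and Il2ra) higher adjusted over the list alone. The erythroid, gamma delta T cell, mammary tumour epithelium, melanoma, myeloid and dendritic cell, and stromal and endothelial lists had under 3 measured genes each and 0 genes past the threshold over all genes. Adjusted over the list alone Trdv4 of the gamma delta list was the 1 exception.

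In B16F10 the treated library had higher levels of cell cycle genes and of several genes of memory and cytotoxic cells, and lower levels of antiviral interferon genes. At 10 CPM or more 60 genes were at least 2-fold higher and 12 at least 2-fold lower of 7895. The higher genes were 94 with doublets kept and 89 with all cells, and the lower ones 13 in each. Ccr2, a chemokine receptor of inflammatory homing (chromosome 9, 124101950 to 124113557), was at 3.54 CPM in the control and 25.1 CPM in the treated library, a log2 ratio of 2.82 (2.68 to 2.98). Gzmm, which encodes granzyme M (chromosome 10, 79689020 to 79695261), was at 17.6 and 83.9 CPM, a log2 ratio of 2.25 (2.18 to 2.32). S100a6, a calcium-binding protein gene of memory T cells, was at 50.7 and 199 CPM (1.98, 1.94 to 2.02). Klre1 (1.85), the centromere protein gene Cenpf (1.85) and the zinc transporter gene Tmem163 (1.80) completed the 6 largest. Ccl5, the chemokine gene that memory CD8 T cells keep transcribed, was at 416 and 1032 CPM, and the memory transcription factor genes Tbx21 (1.46) and Eomes (0.88) were higher as well. On the lower side stood the antiviral genes Ifit3b (-1.83, -1.95 to -1.71), Ifit1 (-1.50, -1.57 to -1.43) and Ifit3 (-1.34, -1.41 to -1.27), which lie together on chromosome 19 between 34583531 and 34650009. Ifit3 and Ifit3b are near-identical copies, so their counts are uncertain. Oasl2, of the same antiviral programme, was at 17.6 and 7.20 CPM (-1.29), Isg15 at 160 and 68.5 CPM (-1.23), and Irf7, the factor that amplifies the response, at -0.94. Tex14 (-1.46) and Sugct (-1.28) were the remaining 2 of the 6 lowest. The comparison is of 1 library with 1 library.

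In 4T1 Gzma, Gzmm, several cell cycle genes, Fos and Jun were higher in the treated library. At least 2-fold differences were seen in 9 of 7836 genes, against 46 with all cells, 45 with doublets kept and 16 with cells picked by a Cd8 UMI. Of the 9 genes 8 were higher, and the lower one, named after its value was seen, was the antibody constant region gene Ighg1. Gzma, which encodes granzyme A (chromosome 13, 113093825 to 113100981), was at 4.31 CPM in the control and 18.5 CPM in the treated library, a log2 ratio of 2.10 (1.97 to 2.24). In B16F10 its ratio was 0.37. Fos, a subunit of the AP-1 transcription factor, was at 4.36 and 12.7 CPM (1.54, 1.40 to 1.68), and its partner Jun at 15.4 and 33.5 CPM (1.12, 1.04 to 1.2). Both were lower in the treated B16F10 library, at -1.12 and -1.19. Gzmm (1.37), Cenpf (1.15) and Nusap1 (1.07) were shared with B16F10. Interferon genes that stood low in B16F10 were slightly higher, with Isg15 at 206 and 258 CPM (0.32), Ifit1 at 0.31 and Usp18, a brake on interferon signalling, at 0.43. On the lower side Cxcr4, a receptor that holds lymphocytes in bone marrow and lymph node, was at 13.9 and 7.48 CPM (-0.89, -1.0 to -0.78). Gstp2 (-0.78), Gm31135 (-0.74), Tmtc2 (-0.72), Gm15564 (-0.71) and Ccnb1ip1 (-0.70) were the other 5 lowest. Gm31135 was near the floor in B16F10, at 0.222 and 0.286 CPM. Here too 1 library stood against 1 library.

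The responses of both models overlapped in part, by a measure that depended on the cells used. Across 11444 genes the log2 ratios of B16F10 and 4T1, which share no library, had a Pearson correlation of 0.484 and a Spearman correlation of 0.422, where genes are not independent replicates. The Pearson value was 0.251 with all cells and 0.181 with doublets kept, and the Spearman value 0.385 and 0.421. The sign was the same for 65.8% of genes. Ratios of at least 1.5-fold in both models went the same way for 198 genes and opposite ways for 21. These counts were 147 and 44 with all cells, 212 and 37 with doublets kept, and 46 and 1 at a mean of 10 CPM or more. The batch of each library is not given in the sources used here, and no test of a difference between models was possible with 1 library per group.

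Cell states were compared by the share of CD8 T cells in each cluster class. Treated libraries held larger shares of memory-like and cycling cells in both models. The interferon-responding share was lower in treated B16F10 cells, and its direction in 4T1 depended on the clustering. Memory-like cells were named by markers such as Ccl5, Cd44, Il2rb and Cxcr3. They made up 10.4% (9.96% to 10.8%) of CD8 T cells in the B16F10 control and 28.7% (28.1% to 29.3%) in the treated library, a ratio of 2.77 (2.60 to 2.94). In 4T1 they made up 8.59% (8.16% to 9.04%) and 17.0% (16.5% to 17.5%), a ratio of 1.98 (1.82 to 2.15). Genes that lead this cluster, such as 1700025G04Rik, also differed between groups. Clustered without the responding genes, the cluster that got this name was led by NK receptor genes and held 4.81% and 17.0% in B16F10 and 1.56% and 4.13% in 4T1. A larger CD8 cluster there, with Cxcr3, Samd3 and Gzmm among its leading genes, met the scoring of no state. Cycling cells, led by Mki67 and Birc5, were 0.736% and 2.73% of CD8 T cells in B16F10 and 1.40% and 3.88% in 4T1. Clustered without the responding genes they were 1.84% (1.66% to 2.04%) and 3.25% (3.03% to 3.48%) in B16F10, and 2.07% (1.85% to 2.30%) and 3.13% (2.89% to 3.39%) in 4T1.

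Interferon-responding cells, led by Rsad2, Ifit1 and Ifit3b, were 5.29% (4.98% to 5.61%) of CD8 T cells in the B16F10 control and 0.842% (0.730% to 0.967%) in the treated library. In 4T1 they were 4.87% (4.54% to 5.22%) and 6.69% (6.34% to 7.06%). The treated over control ratio in B16F10 was 0.159, against 0.460 at resolution 0.5, 0.419 with each model clustered on its own and 0.388 with doublets kept. In 4T1 it was 1.37, but 0.864 (0.827 to 0.903) at resolution 0.5, where the share was lower in both models. Early activated cells, led by the early growth response genes Egr1, Egr2 and Egr3 and by Nr4a1, were 9.17% and 6.79% in B16F10 and 7.66% and 7.0% in 4T1, where the intervals overlapped. Exhausted-like cells, led by Lag3 and Pdcd1, were 7.28% and 8.16% in B16F10 and 5.2% and 5.08% in 4T1, with overlapping intervals in 4T1. The size of this class depended on the clustering, at 3.37% and 3.94% in B16F10 and 3.16% and 3.06% in 4T1 at resolution 0.5, and at 1.65% and 1.95%, and 1.72% and 1.81%, at resolution 1.2, where a cluster with Lag3 among its leading genes was named naive. Naive-like cells fell into 3 clusters, compared singly because 2 of them led with markers of other classes. Cluster 0, led by Gm30948 and Igfbp4, held 32.2% and 24.1% in B16F10 and 25.3% and 17.9% in 4T1. Cluster 2, led by the interferon GTPase genes Iigp1 and Gbp2b, held 16.5% and 10.3% and then 31.2% and 24.3%. Cluster 3, led by Ccr9, held 18.5% and 18.3% and then 15.7% and 18.2%, at the lowest depth of the 3. Outside the CD8 T cells, B-like cells were 3.59% and 4.09% of all cells in B16F10 and 4.03% and 5.51% in 4T1, and CD4-like cells 3.35% and 3.01% and then 6.65% and 8.69%. Myeloid or dendritic-like cells were 1.43% and 2.08% and then 3.21% and 3.25%. The enrichment and the gate of the CD8 sort set these shares of other lineages.

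**Figure D2:**
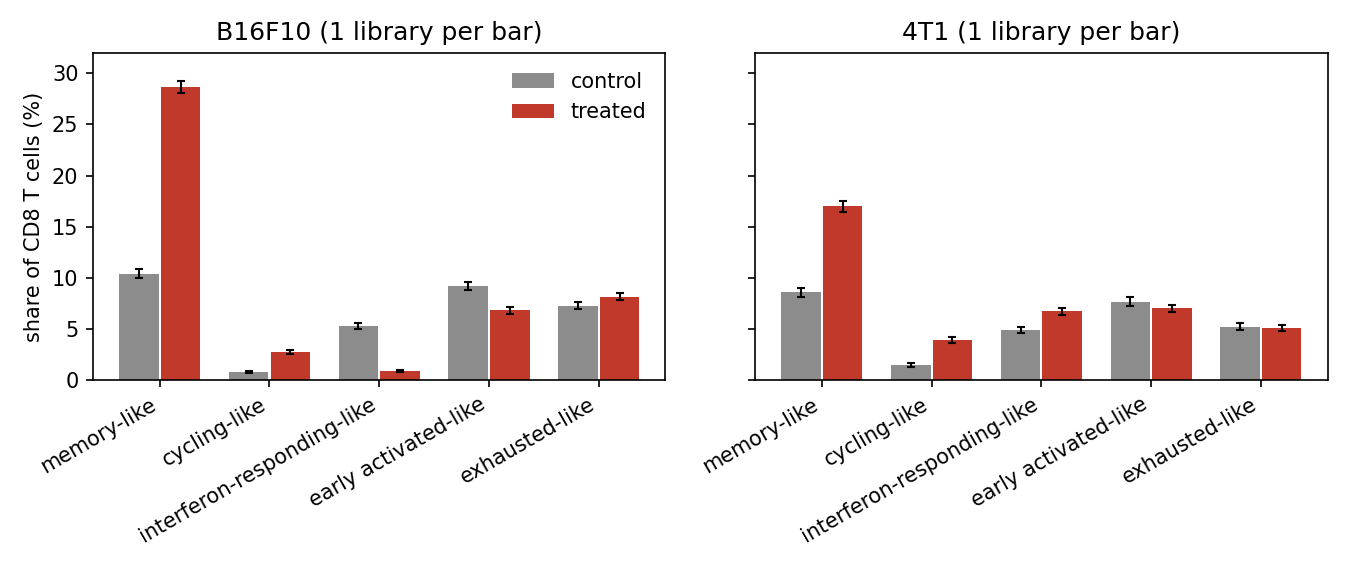
Percent of CD8 T cells in each named class per library, with exact 95% binomial intervals that cover counting error only. Memory-like cells stand at 10.4% and 28.7% in the B16F10 control and treated libraries and at 8.59% and 17.0% in 4T1.

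Shares of cells with at least 1 UMI of a marker gene did not rest on the states named within the CD8 T cells, although the clustering had set which cells count as CD8 T cells. Division markers, Ccl5 and Il2rb were found in more treated than control CD8 T cells, while PD-1 and LAG-3 transcripts were not clearly so. Each cell was thinned to 2500 UMIs, which left out 544, 1172, 418 and 1749 shallow CD8 T cells in the B16F10 control, B16F10 treated, 4T1 control and 4T1 treated libraries. Mki67, a gene of dividing cells, was seen in 0.556% and 1.96% of CD8 T cells in B16F10 and in 0.925% and 2.43% in 4T1, against 0.911% and 3.24%, and 1.47% and 3.97%, without thinning. Top2a, the topoisomerase of replicating cells, was seen in 1.17% and 2.75%, and in 1.87% and 3.87%. Ccl5 was seen in 11.9% and 25.1%, and in 7.04% and 10.6%. The interleukin 15 receptor chain gene Il2rb was seen in 20.1% and 27.3%, and in 17.9% and 19.6%. Cd44, an adhesion receptor of memory cells, was seen in 3.59% and 6.54%, and in 4.56% and 5.06%. Gzma was seen in 0.442% and 0.802%, and in 0.627% and 1.49%, and Gzmb in 0.206% and 0.394%, and in 0.349% and 0.551%. In 4T1 the intervals of control and treated cells overlapped for Cd44 (4.24% to 4.90% and 4.73% to 5.39%) and for Gzmb (0.262% to 0.455% and 0.446% to 0.674%). In B-like cells, which should lack Ccl5, Il2rb and the granzymes, Ccl5 was seen in 1.17% and 5.25%, and in 1.73% and 1.88%. Il2rb was seen there in 0.167% and 0.169%, and in 0 and 0.565%, Gzma in 0 cells of 3 libraries and in 0.0942% of treated 4T1 cells, and Gzmb in 0 cells. Dividing B cells transcribe Mki67 and Top2a, so their shares there are no background. Mki67 was seen in 0.167% and 0.677%, and in 0.145% and 0.188%, and Top2a in 0.669% and 1.18%, and in 1.01% and 0.659%. Cd44, which B cells also transcribe, was seen there in 3.51% and 4.74%, and in 3.04% and 2.35%. The median depth before thinning was 5429, 5483, 6080 and 6047 UMIs in the CD8 T cells and 3188, 3045, 3945 and 3434 in the B-like cells, in the order of the libraries. Pdcd1 was seen in 0.525% and 0.629%, and in 0.698% and 0.784%, with overlapping intervals, and Lag3 in 0.612% and 0.673%, and in 1.27% and 1.15%. Tcf7 was seen in 63.6% and 63.2%, and in 70.8% and 69.5%, and Ccr7, which guides T cells into the node, in 62.3% and 55.3%, and in 74.2% and 72.8%. Tox was seen in 25.3% and 25.8%, and in 25.3% and 24.5%, and Itgae in 14.1% and 13.0%, and in 8.41% and 8.28%. Ly6c2 was seen in 40.5% and 46.5% in B16F10, where its CPM was lower in the treated library, so no order is read from it, and in 61.0% and 63.7% in 4T1. Klrg1 was below 0.1% in each library after thinning. Of the genes fixed as background, Cd79a was seen in 0.206% and 0.372%, and in 0.336% and 0.453%. The myeloid gene Lyz2 was seen in 0.0617% and 0.328%, and in 0.188% and 0.337%. In 4T1 the intervals overlapped for both. The haemoglobin gene Hbb-bs was seen in 0.0206% and 0, and in 0.0194% and 0.0348%. Background of Cd79a and Lyz2 was thus larger in treated cells too, which limits the reading of small shares such as those of Gzma and Gzmb. Without thinning, the shares in B16F10 control and treated and then 4T1 control and treated cells were 2.52%, 4.84%, 4.40% and 7.28% for Top2a, 15.2%, 31.9%, 11% and 16% for Ccl5, and 37.7%, 45.9%, 37.2% and 38.8% for Il2rb. They were 9.64%, 15.6%, 12.2% and 13.1% for Cd44, 1.11%, 2.06%, 1.49% and 3.33% for Gzma, and 0.50%, 0.889%, 0.686% and 1.14% for Gzmb. For Pdcd1 they were 1.41%, 1.61%, 1.88% and 2.15%, for Lag3 1.31%, 1.5%, 2.78% and 2.89%, and for Tox 46.0%, 46.1%, 49.0% and 45.0%. For Tcf7 they were 86.2%, 84.9%, 90.9% and 87.6%, and for Ccr7 85.4%, 78.5%, 93.2% and 89.3%. For Itgae they were 26.8%, 23.2%, 16.4% and 15.5%, for Ly6c2 47.0%, 52.7%, 70.7% and 71.2%, and for Klrg1 0.0951%, 0.143%, 0.145% and 0.221%.

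The last comparison asked whether the response lay in the mix of states or also within each state. The fall of the glucocorticoid-induced gene Tsc22d3 and of Rpl38, Fgfr2 and Tmtc2 was seen within most classes. Most of the cell cycle genes did not pass inside them, with folds that went both ways. Treated and control cells were tested within 8 classes or clusters over both models by edgeR's quasi-likelihood test. The number of genes past an adjusted p of 0.05 was 582 in memory-like cells (332 higher, 250 lower), 331 in cycling cells (211 and 120), 209 in interferon-responding cells (123 and 86), 94 in early activated cells (46 and 48) and 21 in exhausted-like cells (6 and 15). In naive-like clusters 0, 2 and 3 it was 19, 123 and 8. Tsc22d3, Gstp2 and Rpl38 fell in 7 of the 8, Fgfr2, Tmtc2 and Rps29 in 6, and Il31ra, Ddit4 and Cxcr4 in 5. The 8 come from the same 4 libraries and are not independent, so a shift of a whole library would show in all of them. In cycling cells Tsc22d3 was at 0.45 ± 0.164 (adjusted p 0.201). In memory-like cells Tsc22d3 had a log2 fold change of -0.66 ± 0.0538 (adjusted p 0.000461). Plac8, a gene of effector and memory T cells, rose in 6 of the 8, by 0.84 ± 0.0980 in cycling cells (adjusted p 0.00179). Gzmm, Ccl5, Cxcr3 and Tbx21 each rose in 3, the interferon-responding cells among them. In early activated cells Ifng, the gene of interferon gamma, rose by 1.49 ± 0.179 (adjusted p 4.9e-05) and Gzmm by 1.44 ± 0.223 (adjusted p 0.00117). In cycling cells Gzmm rose by 1.60 ± 0.134 (adjusted p 0.000203). In memory-like cells Tbx21, which drives effector fate, rose by 0.47 ± 0.0661 (adjusted p 0.00677). In interferon-responding cells the log2 fold changes were 1.68 for Ccl5, 1.79 for Gzmm and 2.58 for Gzmb. The fit there gave most genes a spread shared across genes, with none of their own. This makes its p-values smaller than the data warrant, so they are not given. Its 209 genes, and its part in the counts of classes, carry the same limit. The class held 1057 control and 200 treated cells in B16F10, and 774 and 1270 in 4T1. It was named by interferon genes, and the mix of memory and other cells inside a class was not compared between groups. A fold within a class thus does not separate a change per cell from a change in that mix. In memory-like cells Ccl5 was at 0.05 ± 0.0594 (adjusted p 0.686) and Gzmm at 0.71 ± 0.163 (adjusted p 0.149). Nusap1, Cdk1, Cdca8, Tk1, Tcf19 and Hist1h1a passed in 0 of the classes in which they were tested, and Stmn1 in 1, the cycling cells (0.30, adjusted p 0.0404). Outside the cycling cells the folds went both ways, many with wide errors, so these tests show neither a change nor its lack. Tk1, at a block log2 of 0.86 in the sum, was at 1.1 ± 0.341 in memory-like cells, 1.22 ± 0.482 in naive-like cluster 0 and 0.87 ± 0.332 in early activated cells, and Cdk1 at 0.95 ± 0.379 in cluster 0. In memory-like cells Cdca8 was at -0.92 ± 0.272, Nusap1 at -1.1 ± 0.809 and Cdk1 at 0.02 ± 0.410, and in exhausted-like cells Nusap1 at -0.72 ± 0.586. In memory-like cells Mki67 rose by 1.79 ± 0.332 (adjusted p 0.0189), Hist1h2ab by 2.01 ± 0.441 (adjusted p 0.0347) and Lockd by 0.79 ± 0.161 (adjusted p 0.0273). Ccr9, lower in the sum, was lower in 2 of the 8, the early activated cells (-0.39, adjusted p 0.0285) and the interferon-responding cells (-0.57). It was higher in cycling cells (1.09 ± 0.225, adjusted p 0.0282) and at -0.02 in naive-like clusters 0 and 3. Cycling cells were deeper in control than in treated libraries, with a median of 17969 against 12570 UMIs in B16F10.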

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

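The tests of depth, of RNA from B cells, of clusters drawn along responding genes and of doublets were chosen only after the result was seen, and that of library number before.

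The type I interferon genes moved apart between the tumour models. Their median log2 ratio of treated over control was -0.63 in B16F10 and 0.21 in 4T1, and the share of interferon-responding cells had a treated over control ratio of 0.159 in B16F10 and 1.37 in 4T1. At resolution 0.5 the ratios of shares were 0.460 and 0.864, no longer on opposite sides of 1, and with each model clustered on its own 0.419 and 1.09. The difference between models was not tested, since each group has 1 library. Summed UMIs of the CD8 T cells were higher in the treated library of both models, with log2 ratios that differed by -0.0106. CPM divides the library total out, so this does not decide whether depth plays a part. This test replaced one at equal summed UMIs, fixed earlier, which leaves ratios of CPM as they are and so decides nothing either. UMIs per cell were not matched. B cell transcripts lay -0.16 apart, in the opposite direction, which argues against RNA from B cells as the source. Batch, host strain and the pool of mice behind each library cannot be told apart from the tumour model with 1 library per group, and a real difference in how interferon signalling responds in each model may equally hold and was not tested.

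Immediate early genes also had opposite signs, with a median log2 ratio of -0.33 in B16F10 and 0.15 in 4T1. Fos, Jun, Fosb, Dusp1 and Cd69 were each lower in the treated B16F10 library and higher in the treated 4T1 library, while Egr1 was at -0.33 and -0.10. The difference between models was not tested. These genes rise within minutes of tissue handling as well as on receptor stimulation, and no test here separates those.

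NK-like cells, which lie outside the comparisons of CD8 T cells, took a larger share of all cells in the treated libraries, by a ratio of 1.66 in B16F10 and 2.67 in 4T1. The shares were 1.22% and 2.03% in B16F10 and 0.37% and 0.97% in 4T1. The sort for CD8 sets these shares, and Cd8b1 was detected in 47.8% of the cells of this cluster, so CD8 T cells with NK receptors are part of it. At resolution 0.5 an NK-like cluster with Cd8b1 in 13.6% of cells held 0.183% and 0.213% in B16F10 and 0.339% and 0.816% in 4T1. No explanation was tested.

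The larger shares of memory-like and cycling cells in treated libraries were weighed against artefacts. Doublets of CD8 T cells hold a mix of the same transcripts and would leave the summed counts unmoved, while the smallest of the memory and cell cycle list medians in summed counts was 0.16, which argues against doublets as the whole source. Clustered without the responding genes, the smallest ratio was 2.66 for the memory-like cluster, but that cluster was led by NK receptor genes and is not the same class, so for memory-like cells the question stays open. For cycling cells the smallest ratio was 1.51, against 2.76 with all genes. The genes left out include cell cycle genes such as Cdk1, Stmn1 and Nusap1, so this cluster is blurred by construction. Its markers had a mean fold of 12.5, against 34.0 in the main clustering. The lower ratio therefore does not decide how much of the larger share comes from clusters drawn along responding genes, which stays open. Control and treated CD8 T cells with a Mki67 UMI after thinning, counted without these states, were 0.556% and 1.96% in B16F10 and 0.925% and 2.43% in 4T1. An effect of the drug on division and memory formation is a hypothesis that these libraries leave open.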

How the results depend on the processing

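Removal by doublet score, leaving out cycling cells, keeping unnamed clusters, clustering without the responding genes, the first scoring of names, and all alternatives for the correlation between models but the one at 10 CPM were tests chosen after the result was seen.

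Of the single values compared across settings 690 stayed the same, 63 moved, 44 lost their side of the threshold and 7 reversed. Of the main values 50 stayed the same and 30 moved. The count of 390 genes over both models was 390 with DESeq2 size factors (389 shared), 377 with DESeq2 (269 shared), 545 with cells picked by a Cd8 UMI, 557 at equal summed UMIs, 490 with high doublet scores removed and 481 with unnamed clusters kept. With no filter on low counts it was 1484, of 23518 genes tested, in a fit that gave most genes a spread shared across genes. For most genes their own spread does not enter such a fit, so 1484 cannot be set beside 390. The count was 254 with doublets kept and 38 with all cells that passed quality (26 shared), and the cause was not tested. With doublets kept, cells with UMIs of other lineages were kept too, in clusters drawn anew. Its CD8 T cells held a cluster of 590 cells led by Klk1, Siglech and Cox6a2, which the first scoring named myeloid or dendritic-like. Values of that setting are therefore not the effect of doublets alone. Without the block edgeR passed 0 genes (263 at an unadjusted p under 0.05), because the spread then holds the difference between models. Leaving out a library leaves no residual degree of freedom with the block, so no such test was made. The block pairs the treated with the control library of each tumour model, and no further paired analysis was possible because the labels give no replicate numbers.

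With cycling cells left out 406 genes passed, 256 of them shared, and of the 24 named genes Nusap1 (-0.11) and Cdca8 (-0.24) reversed, Cdk1, Lockd, Tcf19 and Hist1h1a lost their call and 18 stayed the same. With all cells 13 of the 24 lost their call, and with doublets kept 3. In 4T1 the count of genes at least 2-fold apart was 46 with all cells, 45 with doublets kept and 16 with a Cd8 UMI, against 9. The correlation between models was 0.251 with all cells and 0.181 with doublets kept, where the Spearman value stayed at 0.421. The cause was not tested.

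Under the revised scoring of names, the cluster named memory-like had a share ratio above 1 in every clustering tried. In B16F10 it was 2.52 at resolution 0.5, 2.97 at resolution 1.2, 2.59 with each model on its own, 4.21 with doublets kept, 3.46 with the stricter quality filter and 3.53 without the responding genes. In 4T1 it was 1.54, 2.76, 1.62, 4.91, 3.98 and 2.66 in the same order. In the last 3 settings the cluster was led by the NK receptor genes Klra6, Klra7 and Klre1, so it is another cluster under the same name. With doublets kept the first scoring named it NK-like and gave no memory-like class, so the direction for memory-like cells was not shown there. The cycling ratio in B16F10 was 5.34 at resolution 0.5, 4.77 with the stricter filter and 1.76 without the responding genes, and in 4T1 it was 1.51 without them.

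The shares themselves depended on the clustering. In control libraries memory-like cells ranged from 3.43% to 12.2% in B16F10 and from 0.283% to 12.9% in 4T1, interferon-responding cells from 5.29% to 20.1% and from 4.87% to 33.0%, and exhausted-like cells from 1.08% to 7.28% and from 1.42% to 5.2%.

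Some 4T1 ratios near 1 crossed it. The interferon-responding ratio was 0.864 at resolution 0.5, where the cluster also took in cells led by interferon GTPase genes. In B16F10 it stayed below 1, at 0.460 at resolution 0.5, 0.419 with each model on its own and 0.388 with doublets kept, against 0.159. The early activated ratio was 1.00 without the responding genes, and the exhausted-like ratio was 1.05 at resolution 1.2, 1.04 with each model on its own and 1.28 with the stricter filter. The cause was not tested. Within classes the count of genes was 1092 in memory-like cells at resolution 1.2, 735 in cycling and 178 in early activated cells at resolution 0.5, and 64 in exhausted-like and 90 in interferon-responding cells at resolution 1.2. These counts run over other cells than the main ones. The fits behind 178 and 64 also gave most genes a spread shared across genes.

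Positions of lists among random lists changed side of the central 95% in a few cases. The naive and quiescence list in B16F10 was at percentile 1.02 with all cells, 2.05 with doublets kept and 2.28 with a Cd8 UMI. The homing list in 4T1 was at 1.46 with all cells and 1.53 with doublets kept, and the progenitor exhausted list at 98.7 with doublets kept. With all cells the B cell list in B16F10 was at 95.5 and the CD4 and regulatory T cell list at 69.1. The cause was not tested.

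Depth limits genes near 1 CPM, such as Socs2, Klrg1 and Cd4, whose intervals are wide. Homotypic doublets could not be called.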

Other observations

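The test reported here was chosen before its result was seen, and the comparison of B cell genes by level was added after.

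B cell transcripts were higher in CD8 T cells of the treated libraries. RNA released by B cells would raise the list in every cluster of CD8 T cells alike, and its median log2 ratio was above 0 in 14 of the 16 combinations of cluster and model. The exceptions were the cycling and the interferon-responding cells of B16F10, at -0.16 and -0.24. The medians reached 1.07 in the memory-like cells of B16F10 and ran from 0.16 to 0.75 in 4T1, so the rise was not alike in size. The 16 values come from 4 libraries and are not independent. B-like cells were also a larger share of all cells in the treated libraries. In the B16F10 control library the level of Cd79a in CD8 T cells was 0.0195% of that in B-like cells, and in the treated one 0.0373%. In 4T1 the level of Cd79a was 0.0373% and 0.0525%. For Cd74 it was 0.0497% and 0.0839% in B16F10 and 0.0304% and 0.0538% in 4T1, and for H2-Aa 0.0219% and 0.0578%, and 0.0334% and 0.0605%. Igkc went the other way in 4T1, from 2.21% to 0.731%. Bank1 did not rise either (0.170% and 0.169% in B16F10, 0.317% and 0.291% in 4T1), nor did Ighm in B16F10 (24.1% and 23.7%). The myeloid gene Lyz2 was also seen in more CD8 T cells of the treated libraries after thinning. Its shares were 0.0617% and 0.328% in B16F10 and 0.188% and 0.337% in 4T1. RNA from cells other than B cells was not tested as a source. The rise of Cd74 and H2-Aa may in part come from free RNA, which the genes that did not rise leave a hypothesis.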
